A study of Mus musculus with 2 samples.

How the data were processed

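H3K4me3 ChIP-seq was performed on whole lung of postnatal day 0 mice of the strain B6NTac;B6NCrl/Lap, with 2 biological replicates of pooled male and female animals and a library size range of 300 to 500 that the labels give without a unit. Both replicates form 1 group. Replicate 1 pooled 15 mice, per the labels, and the number in replicate 2 is not stated.

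The data were 4 peak lists in narrowPeak format on the mm10 assembly. Per the deposited readmes, the authors called peaks on each replicate's alignments alone and on both together (the pooled list), and derived the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller, its threshold and the overlap required for replication are not given in the sources used here. All 21000 replicated peaks had the coordinates of one of the 27811 pooled peaks, and 19535 (93.0%) overlapped a peak of both replicates by at least 1 bp. The lists include weak peaks: 58 replicated, 3402 replicate 1 and 2542 replicate 2 peaks had a −log10 q under 2.

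The ratio values in the lists are the signal value of the deposited format, on a scale of its own in each list. They were taken here as the authors' fold enrichment of each peak over background, which the sources used do not state. The −log10 p-value and −log10 q-value of each peak come from the authors' caller, per the deposited format. The score of each peak is a display value up to 1000 that the authors scaled within each list, and it was not used here. Fold enrichment was compared only within a list, since the normalization behind it is not stated and the depth of each library is unknown. A deeper library gives more and wider called peaks, so counts of peaks and widths carry the unknown difference in depth between the replicates.

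Positions were converted to 1-based coordinates. The last peak end was checked against the length of each of the 21 chromosomes of the GRCm38.p6 genome and lay within it. Genes and 141862 transcript starts were taken from GENCODE mouse release 21, with 22028 protein-coding genes. A gene was called marked when a peak overlapped the 1000 bp on either side of any of its annotated transcript starts. Peaks 1000 bp or less apart were joined into domains, and a gene's width was that of the widest domain at its starts. Promoter CpG observed/expected ratios were taken from the genome in the 1001 bp around the gene's outermost 5′ end; 90 genes without such a ratio formed a class of their own in the matching.

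Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only. The share of marked genes in each of 36 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test. The median width of each of the 24 lists with at least 5 marked members was ranked among 10000 random lists of as many marked genes, drawn with a fixed seed, which gave a two-sided permutation p of at least 0.0002. Both families were adjusted by the Benjamini-Hochberg method over the lists, with a threshold of 0.05. No test was made per gene, so no count of single genes past a threshold is given for a list. Genes are not replicates: these p-values describe the lists in these peak lists and not a condition. The lists overlap in a few genes, such as Tcf21 and Hoxa5. Of the list members, 6 symbols (Ahsp, H19, Kcnq1ot1, Meg3, Airn and Xist) matched no protein-coding gene of the annotation and were left out of the tests. The olfactory receptor list was taken by gene symbol.

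The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule took the 10 genes with the widest domains marked in both replicates, the widest 2 marked and the first 2 unmarked members of each list, a fixed set of lung and control genes, the 5 strongest peaks away from starts, and the 3 genes with the strongest peak in a single replicate. Alternatives included each replicate's own list, the pooled list, stricter q-value limits, other windows, other merging distances, the outermost 5′ end of the gene, and random lists matched on 10 equal groups of CpG ratio.

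The functions were tested on simulated data. Marking, joining and overlaps gave the same genes, domains and counts as bedtools 2.31.1. With 12 genes per list, the share test called 50 of 50 simulated lists with all genes marked and 39 of 50 lists in which 10% of genes were given a peak, and 6 of 200 unchanged lists. The width test called 28 of 50 lists with peaks 2 times as wide and 1 of 193 unchanged lists. In each test the adjustment ran over all simulated lists together, many of them altered. These rates therefore need not hold for the families of 36 and 24 lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1 were used.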

Results

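Trimethylation of lysine 4 of histone H3 (H3K4me3), a modification found at active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in whole lung of newborn mice (postnatal day 0). The design held 1 group of 2 biological replicates, each a pool of lungs from male and female animals, and replicate 1 came from 15 mice. No second tissue, age or treatment was included, so the comparisons were those between the replicates, between parts of the genome, and between groups of genes. Replicate 1 had 28439 peaks covering 31.9 Mb and replicate 2 had 25018 peaks covering 26.6 Mb. The list that the authors made by replication across both held 21000 peaks covering 31.4 Mb, with a median width of 1311 bp. The lists hold no read counts, so the sequencing depth of each replicate is unknown. All positions are in GRCm38 (mm10).

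The first comparison asked how far the replicates gave the same peaks. When each replicate's peaks were ranked by fold enrichment and split into 5 equal groups, every peak in the upper 2 groups was found in the other replicate, and those that were not shared were narrow and weak. Of the replicate 1 peaks, 20559 (72.3%, 95% Clopper-Pearson interval 71.8 to 72.8) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 22719 (90.8%, 90.4 to 91.2) overlapped a replicate 1 peak. In the lowest of the 5 groups the share was 19.02% (18.0 to 20.1) in replicate 1 and 64.4% (63.0 to 65.7) in replicate 2. The 7880 unshared replicate 1 peaks had a median width of 273 bp against 1267 bp for the shared ones, and the 2299 unshared replicate 2 peaks had 239 bp against 977 bp. Within replicate 1 the authors' median fold enrichment was 3.47 for unshared and 18.9 for shared peaks, and within replicate 2 it was 3.32 and 11.1. By covered bases, 24.9 Mb lay in peaks of both replicates, a Jaccard index of 0.743. With 1 library on each side, no test between the replicates was possible.

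**Figure D1:**
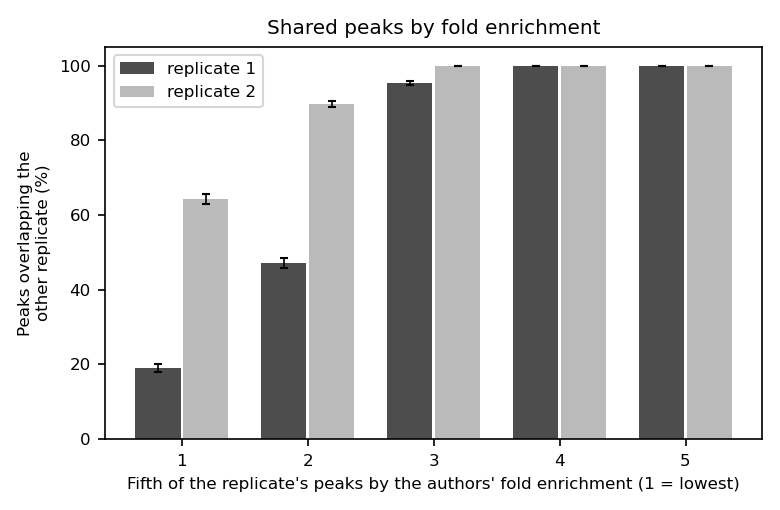
Share of each replicate's peaks (y axis, percent) that overlapped a peak of the other replicate by at least 1 bp, by rank of the authors' fold enrichment within that replicate in 5 equal groups (x axis, 1 = lowest); dark bars are replicate 1, light bars replicate 2, and error bars are 95% Clopper-Pearson intervals. The share was 19.02% and 64.4% in the lowest group and 100% in the upper 2 groups of both replicates.

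The second comparison asked where the mark lay. Of the 21000 replicated peaks, 15908 (75.8%, 75.2 to 76.3) overlapped the 1 kb on either side of an annotated transcript start. A further 2767 (13.2%, 12.7 to 13.6) lay elsewhere in an annotated gene and 2325 (11.1%, 10.7 to 11.5) lay between genes. When the same peaks were placed at random on their own chromosomes 100 times, 10.02% on average were near a start (range 9.44 to 10.5), so the observed share was 7.56 times the random one. Peaks at starts were wider than the rest, with a median of 1562 bp against 593 bp within genes and 632 bp between genes, and they had a median fold enrichment of 25.2 against 4.71 and 5.69. The share was 64.6% in replicate 1's own list and 70.8% in replicate 2's.

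Of the replicated peaks away from any annotated start, the 5 with the highest fold enrichment were nearest to Ppara, Cggbp1, Pura, Pum2 and Arhgap23. The first of these, with a fold enrichment of 47.5, spanned 3839 bp (chromosome 15, 85669573 to 85673411), and its summit lay in an intron of the non-coding gene Lncppara, 61572 bp from the nearest protein-coding start, that of Ppara, a fatty acid-sensing nuclear receptor. The peak next to Pura (chromosome 18, 36285844 to 36288291) had its summit in the coding exon of that gene, and the peak in Arhgap23 (chromosome 11, 97439543 to 97442251) lay in an intron. The peaks near Cggbp1 (chromosome 16, 64872837 to 64874423) and Pum2 (chromosome 12, 8640494 to 8641769) were intergenic. The peaks at Cggbp1, Pura and Arhgap23 did overlap a transcript start in the RefSeq annotation of the same build, and of the 5086 peaks far from starts on the assembled chromosomes 591 (11.6%, 10.8 to 12.5) were within 1 kb of a RefSeq start.

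The third comparison counted the genes that carried the mark. A replicated peak lay within 1 kb of at least 1 transcript start for 14251 of 22028 protein-coding genes (64.7%, 64.1 to 65.3). Of these genes, 167 were not marked in both replicates' own lists. In the replicates' own lists 14095 genes were marked in both, 468 in replicate 1 only and 63 in replicate 2 only. Of those 468 genes, 451 had only peaks with no counterpart in replicate 2, and the highest fold enrichment among them was 7.71. Of the 63 genes, 60 had only peaks without a counterpart, with a highest fold enrichment of 5.66. The genes with the strongest peak in a single replicate were of the remaining kind. For AC140267.1, Lor and Foxq1 in replicate 1, and for Tnnc1, Lmntd2 and Igfn1 in replicate 2, the peak at the start overlapped a peak of the other replicate that ended short of the 1 kb window.

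Marked and unmarked genes differed in base composition at their outermost 5′ end, which is not always the marked start. The median CpG observed/expected ratio in the 1001 bp around the gene's outermost 5′ end was 0.711 in marked and 0.174 in unmarked genes. With genes ranked by this ratio into 10 equal groups, the marked share went from 6.38% (5.39 to 7.49) of 2194 genes in the lowest group to 99.1% (98.7 to 99.5) of 2193 genes in the highest. Nkx2-1, the master regulator of lung and thyroid identity, had 48 CpG sites in that window and a ratio of 0.668, and the 40 bases centred on its start (chromosome 12, 56536889 to 56536928, minus strand) read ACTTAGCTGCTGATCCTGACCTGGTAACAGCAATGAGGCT. Sftpc, which encodes surfactant protein C, was marked with 17 CpG sites and a ratio of 0.248 (chromosome 14, 70524062 to 70524101, minus strand, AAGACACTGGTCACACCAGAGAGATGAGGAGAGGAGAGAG). The domain at Sftpc was shared with Bmp1, and its strongest summit lay downstream of Sftpc. Scgb1a1, the secretoglobin of club cells, had 13 CpG sites and a ratio of 0.211 and was not marked, although replicate 2's own list had a peak of 273 bp at it (chromosome 19, 9087939 to 9087978, minus strand, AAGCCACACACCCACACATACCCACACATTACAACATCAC).

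The fourth comparison asked which groups of genes were marked more or less often than other protein-coding genes, in 36 lists fixed before the data were examined. All 36 lung development regulators were marked, among them Nkx2-1, Foxf1, Tbx2, Tbx4 and Irx5. All 12 alveolar type 1 genes, which mark the flat gas-exchange cells, were marked, as were all 12 genes of surfactant lipid synthesis. So were all 15 Hox genes of paralogue groups 1 to 5, all 30 ribosomal protein genes, all 20 cell cycle genes, all 15 immediate early genes and all 12 hypoxia response genes. Of 20 endothelial genes 19 were marked, including Pecam1, Cdh5, Egfl7 and Sox17 but not Vwf, the gene of von Willebrand factor, and of 20 neural developmental regulators 19 were marked, all but Lhx5, which was marked in replicate 1's own list. Against other genes (64.6 to 64.7% marked), each of these 10 lists was higher by a two-sided Fisher's exact test, with adjusted p from 3.37e-06 for the lung regulators to 0.0272 for the alveolar type 1, hypoxia and surfactant lipid lists.

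In 5 lists genes were marked less often than other genes. Of 14 hepatocyte genes only Apoh was marked, in a domain that it shared with Prkca, and Alb, which encodes albumin, was not (adjusted p = 0.000111, Fisher's exact test). Of 12 granulocyte and mast cell genes only S100a8 was marked, and in replicate 2's own list none was (adjusted exact p = 0.000618), of 12 germline genes only Dazl and Dppa3, of which Dppa3 was not marked in replicate 2's own list (adjusted exact p = 0.0047), and of 16 macrophage and monocyte genes 4, namely Cd14, Fcer1g, Ptprc and Tyrobp (adjusted exact p = 0.00848). Among 1135 olfactory receptor genes 3 were marked, a share of 0.264% with an upper limit of 0.770%: Olfr1033, Olfr94 and, in a domain that it shared with Ifi47, Olfr56. Olfr1033 and Tyrobp were chosen after their values were seen. In the replicates' own lists 7 and 3 of the 16 macrophage genes were marked, and the call was lost with replicate 1 alone and in the pooled list (43.75% in both).

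The other 21 lists did not differ from other genes by Fisher's exact test at an adjusted p of 0.05. In the airway and alveolar lining, 11 of 12 alveolar type 2 genes were marked, all but Sftpa1, which was marked in replicate 1's own list, and so were 9 of 12 ciliated, 7 of 10 neuroendocrine, 3 of 10 club and secretory, and 2 of 8 basal cell genes; Trp63 and Krt5 were among the unmarked basal genes. In the supporting tissue the counts were 12 of 15 for fibroblast and mesenchyme, 13 of 15 for smooth muscle and pericyte, 12 of 13 for elastic fibre and matrix, 4 of 7 for mesothelial and 6 of 6 for lymphatic endothelial genes. Blood cell lists gave 5 of 14 lymphocyte and 4 of 11 erythroid genes. Lists of other tissues gave 4 of 12 cardiomyocyte, 5 of 12 skeletal muscle, 9 of 14 neuron and 5 of 7 thyroid genes, with Myod1 and Neurod1 unmarked. The remaining counts were 2 of 8 for pluripotency, 11 of 16 for Hox groups 9 to 13 (15 and 9 in the replicates' own lists), 8 of 8 for glucocorticoid response and 11 of 12 for imprinted genes. Several of these lists were called under other settings of the same test: club and secretory genes lower with peaks over the start itself (0%), with outermost 5′ ends (10%) and with a −log10 q of at least 5 (20%), basal, lymphocyte and pluripotency genes lower in replicate 1's own list, the pooled list and a window of 2.5 kb, and lymphocyte and pluripotency genes also with outermost 5′ ends. Erythroid and skeletal muscle genes were called lower with peaks over the start itself (27.3% and 16.7%), alveolar type 2 genes higher in replicate 1's own list, the pooled list and the 2.5 kb window (100%), and imprinted genes higher in that window (100%).

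Both pools held marked genes of both sexes, as their labels state. Xist, the RNA that silences an X chromosome in females, had a domain of 3051 bp (replicates 3487 and 1347 bp), and the Y-linked genes Ddx3y (1118 bp), Eif2s3y (1358 bp) and Uty (1195 bp) were marked in both replicates. Of the 5 protein-coding X and Y markers 4 were marked, all but Usp9y.

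When the lists were compared with 10000 random lists matched on promoter CpG ratio in place of Fisher's test, 2 of the 10 higher lists (lung development regulators and endothelial) and 2 of the 5 lower lists (germline and olfactory receptor) were still called, and the alveolar type 2 and imprinted lists were called higher and Hox groups 9 to 13 lower, whereas in replicate 1's own list and in the pooled list Hox groups 9 to 13 were called higher (93.75%). Lists that lost the call under matching at 100%, such as alveolar type 1 (84.6% in matched lists) and cell cycle (96.9%), could not have been higher. Their loss therefore does not show that CpG content accounts for the whole of their mark. Matched lists were marked more often than other genes (64.6 to 64.7%), so a part of their higher share went with CpG content. The 36 lung development regulators, also at 100% (86.4% in matched lists), kept the call. The neural developmental regulators lost it at 95% against 96.8% in matched lists. With the gene's outermost 5′ end in place of all transcript starts, the endothelial, hypoxia and neural regulator calls were lost.

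**Figure D2:**
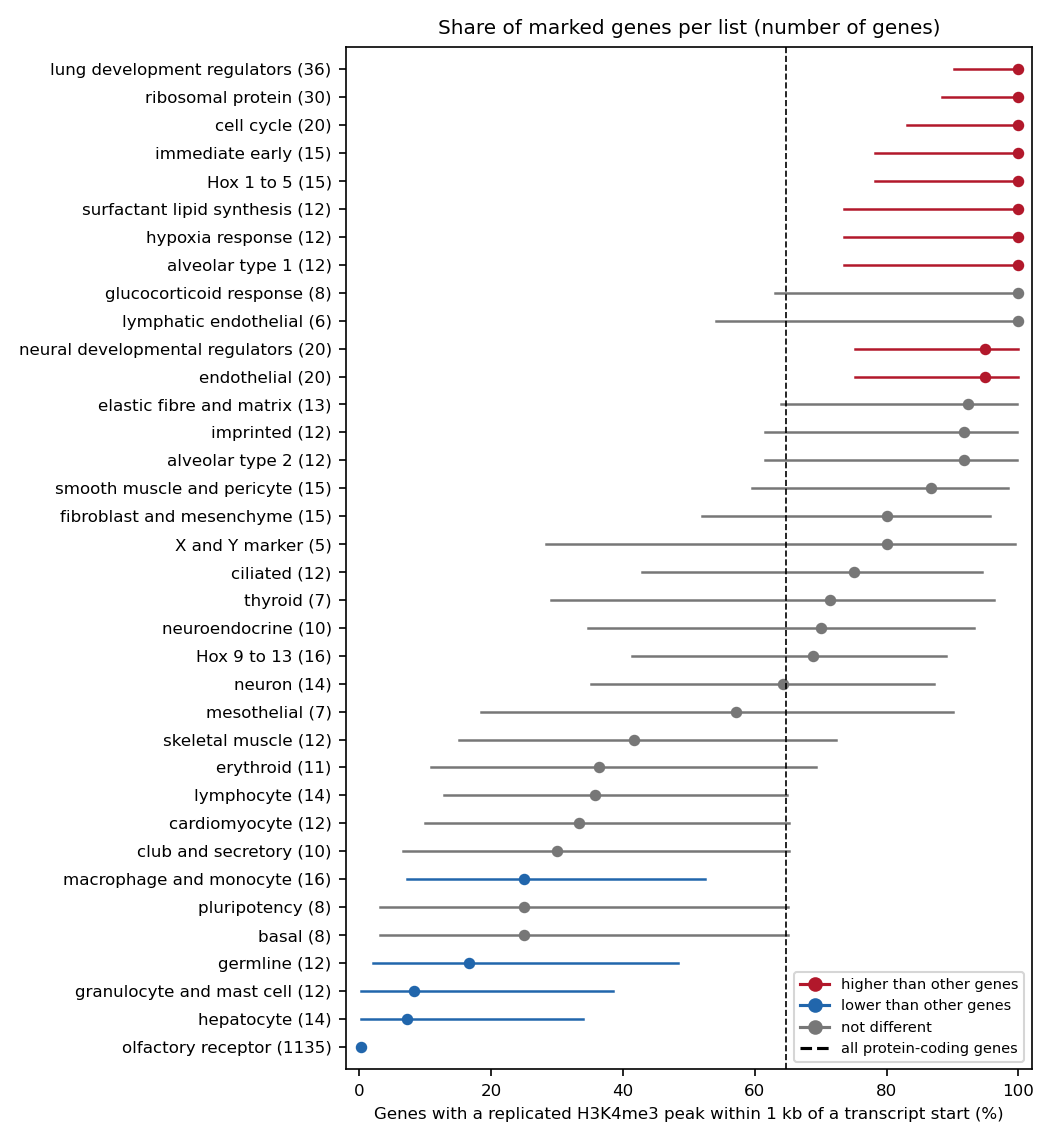
Share of each list's genes with a replicated H3K4me3 peak within 1 kb of a transcript start (x axis, percent), with the number of genes tested after each name; points are shares, horizontal lines 95% Clopper-Pearson intervals, and the dashed line is the share of all 22028 protein-coding genes (64.7%). Red lists were higher and blue lists lower than other genes by Fisher's exact test after adjustment over the 36 lists, from 100% of 36 lung development regulators to 0.264% of 1135 olfactory receptor genes.

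The fifth comparison concerned the width of the marked region, because very wide H3K4me3 domains are known at genes of cell identity. The widest domain in the newborn lung, 21137 bp, lay at Nr2f2, a nuclear receptor of veins, lymphatics and mesenchyme (chromosome 7, 70350187 to 70371323; replicates 20798 and 22390 bp, SD 1126). It was followed by Tbx2 (15804 bp), Irx5 (14363 bp), Tbx3 (14262 bp), Nfib (14256 bp), Nkx2-1 (14213 bp), Zeb2 (13397 bp), Hoxa2 in a domain shared with Hoxa1 (13057 bp), Tbx5 (13001 bp) and Foxf1 (12587 bp). All 10 encode transcription factors. The median over the 14251 marked genes was 1825 bp.

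The Nkx2-1 domain ran from 56524235 to 56538447 on chromosome 12 and measured 12457 and 11730 bp in the replicates (SD 514). It covered the whole gene and the annotated 5′ end of the neighbouring Sfta3-ps, and the summit of its strongest peak lay in an intron of Nkx2-1. The Foxf1 domain (chromosome 8, 121078567 to 121091153; replicates 13229 and 12517 bp, SD 503) had its summit upstream of the gene. The replicates differed more at Nfib (16750 and 9707 bp) and Zeb2 (14617 and 8295 bp).

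**Figure D3:**
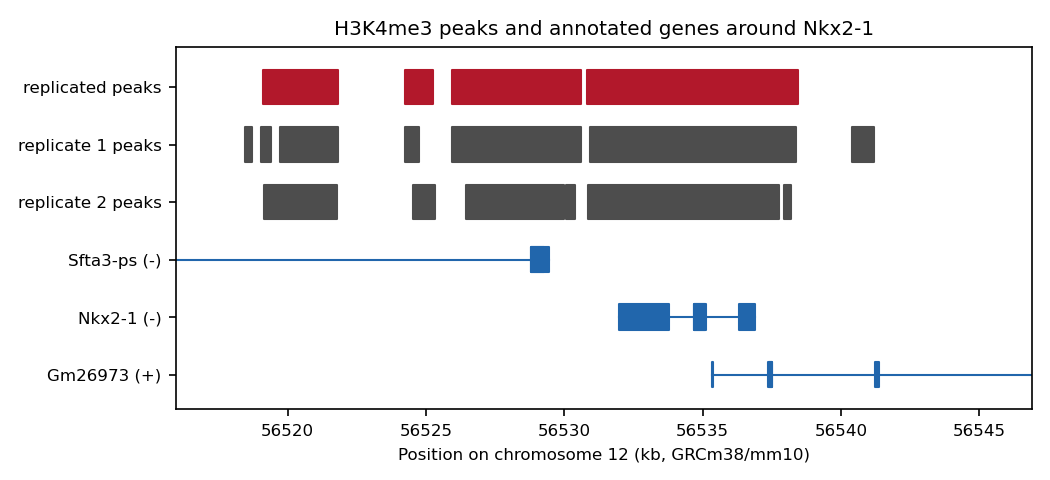
Map of the region around Nkx2-1 on chromosome 12 (x axis, position in kb, GRCm38/mm10); red bars are replicated peaks, grey bars the peaks of each replicate's own list, and blue boxes and lines the exons and extent of annotated genes with their strand. The replicated peaks between 56524235 and 56538447, joined where 1 kb or less apart, made the 14213 bp domain that covers Nkx2-1.

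Genes of lung regulation had wide domains. The 36 lung development regulators had a median of 6299.5 bp, and 26 of them were among the widest 5% of marked genes, those of at least 4252 bp. Besides the genes above, Foxa1 had 11182 bp, Gata6 9482 bp, Irx2 9373 bp, Id2 9007 bp and Tbx4 6433 bp (replicates 9699 and 6277 bp), whereas Sox2 had 1952 bp (replicates 4851 and 1500 bp) and Etv4 1724 bp; these genes other than Tbx4 were chosen after their values were seen. The 8 glucocorticoid response genes had a median of 5560 bp (replicates 6502 and 5183 bp, against 6236.5 and 5915.5 bp for the lung regulators), with Sgk1 at 8813 bp and the receptor gene Nr3c1 at 7305 bp. The 15 immediate early genes had 4268 bp, led by Zfp36 (7803 bp) and Ier2 (6312 bp). These lists and the alveolar type 1, endothelial and imprinted lists were wider than 10000 random lists of marked genes in a two-sided permutation test on random lists (p = 0.0002, the smallest that 10000 random lists can give; adjusted p = 0.000686).

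The alveolar type 1, alveolar type 2 and endothelial lists were wide as groups, though single members were narrow. The 12 alveolar type 1 genes had a median of 4315 bp, with Rtkn2 (7417 bp) and Cav1 (6759 bp) the widest, Ager at 3401 bp (replicates 3505 and 3049 bp) and Hopx at 2390 bp (2427 and 2038 bp). The 11 marked alveolar type 2 genes had a median of 3270 bp (adjusted permutation p = 0.0016). Slc34a2, a phosphate transporter, had 9155 bp and Sftpc 5948 bp, the latter in a domain shared with Bmp1 whose strongest summit lay downstream of Sftpc. Sftpb, which encodes surfactant protein B, had 940 bp (2619 and 220 bp). The 19 marked endothelial genes had 3740 bp, with Egfl7 at 7941 bp, Sox17 at 7659 bp, Cdh5 at 5013 bp (5485 and 4633 bp) and Pecam1 at 3578 bp (4467 and 3287 bp).

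Mesenchymal, metabolic, imprinted and anterior Hox lists were wider too. Fibroblast and mesenchyme genes had a median of 3077 bp (adjusted permutation p = 0.00336), with Tcf21 at 7305 bp and Pdgfra at 6796 bp. Elastic fibre and matrix genes had 2998.5 bp (adjusted permutation p = 0.00517), with Eln, the elastin gene, at 4844 bp. Hypoxia response genes had 3240.5 bp (adjusted permutation p = 0.0012), above the medians of 2657 and 2649.5 bp in the replicates' own lists, with Epas1 at 6588 bp. Surfactant lipid synthesis genes had 2670.5 bp (adjusted permutation p = 0.0323; replicates 3360.5 and 2565 bp), with Scd2 at 6299 bp. Imprinted genes had 3915 bp, with Gnas at 6178 bp and Mest at 5697 bp, and Hox groups 1 to 5 had 2938 bp (adjusted permutation p = 0.00583).

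Of the 24 lists with at least 5 marked members, 3 had narrower domains than random lists. Ciliated cell genes had a median of 1011 bp (adjusted permutation p = 0.0048), with Ccno at 3541 bp and the master regulator Foxj1 at 1953 bp (1842 and 1839 bp). Neuroendocrine genes had 888 bp (adjusted permutation p = 0.0048), with Ascl1 at 2999 bp. Hox groups 9 to 13 had 871 bp (adjusted permutation p = 0.000686), with Hoxa13 at 3270 bp (2875 and 1354 bp). The other 9 lists did not differ, with medians of 3075 bp (lymphocyte), 2320 bp (neural developmental regulators), 2020 bp (lymphatic endothelial), 2011 bp (ribosomal protein), 1845 bp (cell cycle), 1719 bp (smooth muscle and pericyte), 1642 bp (skeletal muscle), 1537 bp (neuron) and 1336 bp (thyroid).

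The neuroendocrine call was lost in replicate 2's own list (1003 bp), with peaks of a −log10 q of at least 5 (1372.5 bp) and with peaks over the start itself (1857 bp), and the call of Hox groups 9 to 13 was lost at that q limit (1440 bp) and with peaks joined over 3 kb (1467 bp). The alveolar type 2 and surfactant lipid calls were lost when only touching peaks were joined (2038 and 2385.5 bp), whereas the neural developmental regulators were called wider in replicate 1's own list (2644 bp), in the pooled list (2532.5 bp) and with peaks joined over 3 kb (2865 bp), and the lymphocyte list with shared domains left out (3075 bp). Cardiomyocyte, macrophage and monocyte, and mesothelial genes had under 5 marked members in the replicated list and were not tested there. These lists were called narrower in replicate 1's own list and in the pooled list, and cardiomyocyte genes also with a window of 2.5 kb. At Prox1 (7230 bp, replicates 2978 and 2643 bp) and Slc17a7 (2500 bp, 534 and 558 bp) the joined replicated peaks were much wider than the domain in either replicate.

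**Figure D4:**
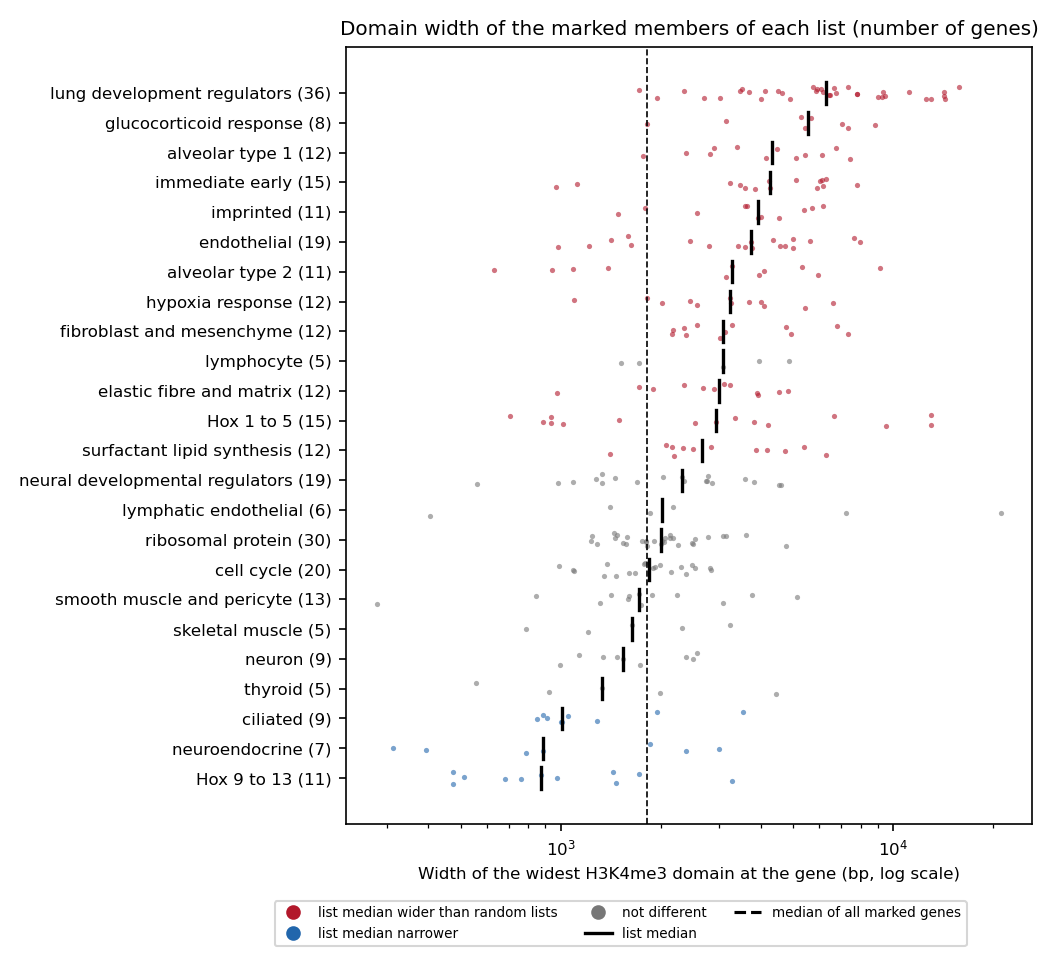
Width of the widest H3K4me3 domain at each marked member of a list (x axis, bp, log scale), with the number of marked genes after each name; points are genes, vertical bars list medians, and the dashed line the median of all 14251 marked genes (1825 bp). Red lists were wider and blue lists narrower than random lists, from a median of 6299.5 bp for lung development regulators to 871 bp for Hox groups 9 to 13.

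The last comparison gave the spread of a gene's width between the replicates' own lists. It is not the error of the width in the replicated list, which can lie outside both replicates, as at Nkx2-1 (14213 bp, replicates 12457 and 11730 bp). Across the 14095 genes marked in both replicates, the log10 widths correlated with a Pearson's r of 0.898 and a Spearman's rho of 0.906; this correlation is across genes, which are not independent replicates. The typical gene had an SD of 153 bp between the replicates and a ratio of 1.14 between the wider and the narrower. Domains were wider in replicate 1 for 79.8% of genes, with medians of 1840 and 1623 bp.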

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

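The comparison of the pooled peaks with random positions, and that of the replicate 1 peaks far from any replicate 2 peak, were tests chosen after the results were seen; the other 2 tests of this part were written before theirs.

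The pooled list, which no comparison above used as its main list, held 6811 peaks outside the replicated list, and these lay near transcript starts more often than random positions did. Of the 6801 on chromosomes, 2052 (30.2%, 29.1 to 31.3) were within 1 kb of a start, against 7.003% on average (6.13 to 7.75) when they were placed at random, a ratio of 4.31. They were narrow (median 270 bp) and weak (median fold enrichment 2.91, against 17.5 for the replicated peaks on the same scale). Of them 3536 overlapped a peak of replicate 1 only, 1042 of replicate 2 only, 50 of both and 2183 of neither, and the pooled list marked 349 protein-coding genes that the replicated list did not.

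A related pattern was the 7880 replicate 1 peaks that no replicate 2 peak overlapped. Background placed at random was argued against: 30.5% of those on chromosomes (2403 of 7870) were within 1 kb of a transcript start, against 6.52 to 7.64% for random positions, and among the 4986 that were over 1 kb from any replicate 2 peak the share was 24.6%, against 6.10 to 8.04%. Fragments at the edges of shared domains could be part of the pattern, since 36.6% (35.5 to 37.7; 2884 of 7880) were within 1 kb of a replicate 2 peak; for these peaks, fragments and separate weak sites cannot be told apart, because the lists hold no reads between peaks. Background that follows open chromatin and a difference in depth also stay open, since the depth of the libraries is unknown. Both replicates belong to 1 group, so no biological explanation was tested.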

How the results depend on the processing

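Of the alternatives, RefSeq starts (73.8% of peaks near a start), protein-coding transcripts only (63.9% of genes marked) and, for the share of marked genes in lists, leaving out shared domains and a permutation test on random lists without CpG matching (15 lists called in each) were tests chosen after seeing the data. Of replicate 1 peaks 66.2% were shared when 50% of the peak had to overlap, 62.4% with 50% of both peaks, 77.2% and 86.3% with a −log10 q of at least 2 and 5, 87.6% among the top 20000 and 79.4% as domains; for replicate 2 the values were 87.7, 70.9, 93.3, 97.99, 93.96 and 92.1%. Peaks near a start made 64.6 to 70.8% of the lists without 1 replicate, 64.6% of the pooled list, 69.1% with the start base alone, 81.4% within 2.5 kb and 65.6% with outermost 5′ ends. Genes marked were 64.3 to 66.1% without 1 replicate, 66.3% in the pooled list, 62.9% with the start base alone and 61.0% with outermost 5′ ends. By share 15 lists were called, 15 and 19 without 1 replicate and 15 to 20 under other settings, but 7 with random lists matched on CpG, of which 4 were among the 15. By width 15 lists were called, 14 and 19 without 1 replicate and 13 to 19 in all; all 12 wider lists stayed wider except with a merge distance of 0 bp, where 10 did. With a merge distance of 3 kb the width correlation was 0.878 (rank 0.888), and with a −log10 q of at least 5 it was 0.906 (rank 0.912). Of 360 comparisons of a list's share 319 kept their side of the threshold, 24 gained a call, 14 lost it and 3 reversed. A changed direction counted as reversed only where the list was called in at least 1 of the settings compared. Lists called in neither could change direction and count as kept. With CpG matching the macrophage share of 25% was no longer lower (adjusted permutation p = 0.986), the 68.75% of Hox groups 9 to 13 turned lower (adjusted permutation p = 0.0158), though called higher at 93.75% without replicate 2 and in the pooled list (adjusted exact p = 0.038 and 0.0385), and the 95% of neural regulators was no longer higher (adjusted permutation p = 1). By the same rule, of 258 comparisons of a median width 247 kept their side of the threshold, 4 gained a call, 6 lost it and 1 reversed, neuroendocrine genes at 1857 bp with the start base alone (adjusted permutation p = 0.988). These comparisons cover only the 24 lists tested in the main setting. Outside them, cardiomyocyte, macrophage and monocyte, and mesothelial genes were called narrower without replicate 2 and in the pooled list. Cardiomyocyte genes were also called narrower within 2.5 kb. Of 767 widths of named genes 577 stayed within the SD of the replicates and 190 moved, and 14 unmarked named genes were marked under some alternative, among them Scgb1a1, Sftpa1, Vwf and Hoxa9. Since random lists without matching gave the same 15 calls (10 higher, 5 lower), the CpG-matched changes of share follow from the matching and not from the change of test. Lists at 100% could not have been higher, so their loss of a call does not show that CpG content accounts for the whole of their mark. Matched lists for those that lost the call were marked at 76.2% (hypoxia response) to 96.9% (cell cycle). These shares were above the 64.6 to 64.7% of other genes, so a part of the higher share went with CpG content. For the other settings the cause was not tested. No paired analysis was possible because there is only 1 group, and the lists hold no counts, so what depth limits could not be measured.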

Other observations

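The comparison of fold enrichment between lists, the ratio of lung to neural regulators, the CpG tests of single lists and the test of unmarked immune genes were tests chosen after the results were seen. The CpG test of the less marked lists was first written for all 5 together, with a minority of lists staying lower as the sign of a cause; 2 of 5 stayed, and it was split by list after that.

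Most genes of the Hox clusters, which pattern the body axis, had a mark within 1 kb of a start. All 10 genes of the b cluster were marked, 9 of 11 in the a cluster (not Hoxa9 and Hoxa10), 7 of 9 in c (not Hoxc8 and Hoxc12) and 7 of 9 in d (not Hoxd10 and Hoxd12). Of non-coding genes, 13.4% of 5854 lincRNA, 33.3% of 2959 antisense, 52.0% of 790 processed transcript and 92.1% of 190 bidirectional-promoter genes were marked, and 1.28% of 9941 processed pseudogenes; differences were not tested. Among those away from the starts of protein-coding genes the shares were 7.93% of 5371 lincRNA, 8.50% of 1694 antisense and 27.6% of 424 processed transcript genes. Among imprinted non-coding genes, left out of the list tests, domains measured 2903 bp at Meg3, 2763 bp at Kcnq1ot1, 2553 bp at Airn and 1276 bp at H19.

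Within the replicated list, the authors' fold enrichment of the peak at a gene was lower than in random lists of marked genes for 9 of 24 lists and higher for 1. All marked genes had a median of 30.5. Lower medians were found for alveolar type 2 genes (9.64, adjusted permutation p = 0.0048), smooth muscle and pericyte (9.19), neuron (6.95), Hox groups 9 to 13 (7.17) and neural developmental regulators (9.09), all with the same adjusted permutation p. Ciliated genes had 10.7 (adjusted permutation p = 0.0114), neuroendocrine 8.07 (adjusted permutation p = 0.0133), endothelial 14.9 (adjusted permutation p = 0.00754) and Hox groups 1 to 5 17.4 (adjusted permutation p = 0.0461). The lists with narrower domains (ciliated, neuroendocrine and Hox groups 9 to 13) were all among the lower ones. For them, narrow domains and weak peaks cannot be told apart. The alveolar type 2, endothelial and Hox 1 to 5 lists were lower as well, but had wider domains. Glucocorticoid response genes had 48.2 (adjusted permutation p = 0.0056). With random lists matched on CpG ratio the endothelial and Hox 1 to 5 lists were no longer called (matched medians 23.5 and 27.9, adjusted permutation p = 0.132 and 0.0881), which does not show that CpG content removes the difference, and the lymphatic endothelial and thyroid lists were called lower.

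In 12 lists, domains were wider than at other marked genes. Promoter CpG content at the gene's outermost 5′ end was argued against as the whole cause, since 12 of 12 lists stayed wider than random lists matched on it. Some domains lay at another start, as at Sgk1 and Nr3c1, and CpG content there was not matched and remains open. Neighbouring promoters joined into one domain were argued against for protein-coding neighbours only, since 12 of 12 stayed wider with genes that share a domain with another protein-coding gene left out. Domains joined across non-coding promoters, as at Nkx2-1 and Sfta3-ps, stayed in that test and remain open. When only touching peaks were joined, 10 of the 12 lists stayed wider. The alveolar type 2 and surfactant lipid lists did not (2038 and 2385.5 bp, adjusted permutation p = 0.437 and 0.0665), so joining of peaks remains open for them. That developmental regulators are wide whatever the tissue was argued against only as the whole cause for the lung regulators, whose median was 2.72 times that of the neural regulators (two-sided permutation p = 0.00059; 2.36 to 3.75 times in 10 settings), medians known before the test; a part of it stays open, since the neural regulators were themselves called wider than random lists without replicate 2, in the pooled list and with peaks joined over 3 kb (adjusted permutation p = 0.0112, 0.0345 and 0.0140), though not without replicate 1, where their median of 1579.5 bp was under the 1618 bp of all marked genes. Differences in peak calling between strong and weak sites stay open, and with 1 group no other biological explanation was tested.

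In 5 lists, genes were marked less often than other genes. Promoter CpG content, taken at the outermost 5′ end, may account for the macrophage list, with 25% marked against 20.7% in lists matched on it (permutation p = 0.877). For the granulocyte list, with 8.33% against 20.6% (permutation p = 0.491), the test cannot decide, since matched lists of 12 genes held few marked genes. By itself, CpG content does not account for the germline and olfactory receptor lists, with 16.7% and 0.264% against 67.9% and 11.9% (larger adjusted permutation p = 0.0018). For the hepatocyte list, with 7.14% against 31.6%, CpG content and a lower share of its own cannot be told apart with 14 genes (permutation p = 0.0276, adjusted permutation p = 0.0903). A mark of resident immune cells just under the replication threshold also cannot be told apart from its absence: 4 of 32 unmarked immune genes (12.5%; Cebpe, Csf1r, Laptm5 and Spi1, named after their values were seen) had a peak in another list, against 0 of 23 unmarked hepatocyte and germline genes (two-sided Fisher's exact p = 0.131), and these counts are small. The design has 1 group, so no biological explanation was tested.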
